A study of Homo sapiens with 16 samples.

How the data were processed

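RNA was sequenced from 16 libraries of MDA-MB-231, an established triple-negative breast cancer cell line. Per the labels, the libraries fall into 6 groups and 3 experiments. In the state sort, cells with the SDorm reporter pair (NANOG-EGFP and a pulse-chase of mCherry-tagged histone H2B) were separated by fluorescence-activated sorting into activated breast cancer stem-like cells (A-BCSC, reporter-high) and quiescent ones (Q-BCSC, reporter-low), with 3 libraries each. In the silencing experiment, unsorted cells were harvested 48 h after transfection with siRNA, either against ENO1 (siENO1) or as a negative control (siNC), with 2 libraries each. In the reporter sort, cells were separated into NANOG-EGFP-positive and NANOG-EGFP-negative fractions, with 3 libraries each. The series design calls the replicates of the state sort and of the silencing experiment biological. For the reporter sort nothing says whether the 3 libraries of a group came from separate cultures, so its p-values measure the spread between these libraries, which may be technical.

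The deposited tables hold whole-number counts per gene, which the authors did not scale. The deposited FPKM tables divide the same counts by gene length and by a library total. The totals implied by the FPKM values were checked against the summed counts: their ratio was 0.950 to 1.07 in the state sort and 0.966 to 1.04 in the reporter sort. Against TMM-scaled totals the ratio was 0.998 to 1.02 and 0.974 to 1.02, so the divisor in both sorts lay nearer a scaled total. In the silencing experiment only totals relative to siNC replicate 1 could be compared, and their ratio to the summed counts was 1. The count tables were used for every comparison, and the FPKM tables only for this check. Per the labels' protocols, all libraries were strand-specific and poly(A)-selected and were read as paired ends of 150 bases. The state sort and the silencing experiment used RNA of integrity number 7 or more, 1 µg of RNA, inserts of about 300 bases and a NextSeq 2000, and the reporter sort used a NovaSeq X Plus. Per the submitters' processing notes, the state sort was quantified on Ensembl release 94 and the silencing experiment on Ensembl release 110 of GRCh38, and the reporter sort on hg38. The gene IDs of the reporter sort were the same set as those of release 94. The aligner, the counting tool and its strand setting are not given in the sources used here, so genes that overlap another gene or have a near-identical copy are uncertain. Gene symbols and coordinates come from the deposited annotation tables.

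Each experiment was fitted alone, because the tables were quantified separately. Levels are CPM, each count as a share of the TMM-scaled library size within an experiment, so a level in one experiment is not on the same scale as in another. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), and groups were compared with edgeR's quasi-likelihood test, two-sided and without a replicate block. The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Summed counts per library were 32279573 to 37687195 in the state sort, 13255775 to 16111534 in the silencing experiment and 21439138 to 26802722 in the reporter sort. For a gene with 0 counts in a group, a bound on the fold was computed against a floor of 3 counts over the group. For 1 to 3 counts over a group, the ratio has an exact 95% counting interval. Floors and intervals cover counting error only. Before averaging, each pair of libraries of a group was checked for identity on genes with a summed count of at least 10. The chi-square per gene was 5.64 to 12.2 in the state sort, 10.5 and 17.7 in siNC and siENO1, and 2.17 to 2.94 in the reporter sort, so no pair was a copy.

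Before the data were examined, 35 gene lists were fixed for metabolism, cell cycle, quiescence, stemness, cell identity, stress, signalling and the cell types that a sample could hold by contamination. They were tested with limma's camera on the edgeR object with a preset correlation between genes of 0.01, two-sided, for lists with at least 5 tested members, and adjusted by Benjamini-Hochberg over these lists. ENO1 was left out of its list in the silencing experiment. Members past the threshold were counted over all genes tested and also adjusted over the list alone. Camera was repeated with a correlation estimated from the residuals. That setting also takes its p-values on the residual degrees of freedom, which are few in these experiments. A call can thus be lost with it even where the members are not correlated. In splits that mixed the groups, the preset called 8 to 17 lists in the state sort and 9 to 12 in the reporter sort, and the estimated correlation called 0. These splits keep part of the real difference between the groups, so they do not show how either setting behaves without one. A call with the preset alone is still read with caution, since the preset assumes the same small correlation for every list. As another test, limma's fry was run.

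The named genes were also chosen by a rule fixed before the data were examined. ENO1, NANOG, MKI67, CDKN1A, CDKN1B, CD44, ALDH1A3, SOX2, POU5F1 and MYC were reported in every comparison. The 10 largest rises and the 10 largest falls were taken among protein-coding genes past the threshold with a mean of at least 5 CPM in a group and no overlap between the groups' libraries. For each list, up to 3 tested members with the smallest p in the direction of the list were named. Genes outside this rule were chosen after their values were seen. In the state sort these are TXNIP, NR2F1, IL11, OAS1, IFIT5, CXCR4, TIE1, COL1A1, ALAS2, TRAC, CD8A, PRF1, MS4A1, HBB and CD14. In the reporter sort they are IL11, LDHB, PGAM1, IGFBP3, F3, PECAM1, TEK, COL1A1, DCN, PTPRC and BCL2A1. The levels of HIST1H2BB outside the state sort were added in the same way. Comparisons were set against each other over genes tested in both, matched by Ensembl gene ID. Pearson and Spearman correlations of log2 fold changes describe these genes, which are not independent. Overlaps of calls stand beside n1 × n2 / N, and camera tested the 200 rising and the 200 falling genes with the smallest p of one comparison in another. No library is shared between comparisons.

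The alternatives, also fixed before the data were examined, were DESeq2 size factors, upper-quartile scaling, no filter and a strict filter at 1 CPM on low counts, a replicate block, the DESeq2 Wald test, limma-voom, a fold of at least 2, 100 or 500 genes in place of 200, genes of at least 5 CPM or protein-coding genes in the correlations, and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the other group. A restriction to genes of at least 1 CPM in siNC or EGFP-negative and a crossed block were added after seeing the data. The steps were tested on simulated data with about 200 changed genes per experiment. In the simulated state sort (17477 genes), 91% of 2-fold and 100% of 4-fold changes were recovered and 6.37% of calls were false. In the simulated silencing experiment (14633 genes), the shares were 80.2%, 98.9% and 7.37%, and in the simulated reporter sort (16725 genes) 95.1%, 100% and 4.41%. In each simulation the list made to rise was called and none of the unchanged lists was. The simulated genes varied independently and few of them changed, so these runs do not show how often lists of correlated genes are called falsely in the data. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Reads were not used here, so reporter transcripts were not measured.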

Results

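The data are gene counts from MDA-MB-231 cells in 3 separate experiments. The state sort gave 32279573, 37687195 and 32913198 counts in Q-BCSC replicates 1, 2 and 3 and 36530970, 35131049 and 35683392 in the A-BCSC replicates. The silencing experiment gave 13255775 and 16111534 in siNC and 13922851 and 15056521 in siENO1. The reporter sort gave 23822729, 26802722 and 26176504 in EGFP-negative and 24001113, 24065740 and 21439138 in EGFP-positive. Mitochondrial genes took 1.79% ± 0.0614 of counts in Q-BCSC, 4.96% ± 0.301 in A-BCSC, 5.00% ± 0.232 in siNC, 4.97% ± 0.426 in siENO1, 2.99% ± 0.0597 in EGFP-negative and 4.08% ± 0.124 in EGFP-positive (mean ± SD; n = 3, or 2 for the siRNA groups). Values below are given in the same form.

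The state sort asked how activated stem-like cells differed from quiescent ones. ENO1 (ENSG00000074800; GRCh38 chromosome 1, 8861000 to 8879250), the glycolytic enzyme enolase 1, was 2.26-fold higher in A-BCSC, at 3918 ± 36.5 CPM against 1733 ± 92.7 in Q-BCSC. Genes of DNA replication and mitosis, all 13 mitochondrially encoded protein genes and many YAP targets were also higher in A-BCSC. Immediate early genes, NF-kB targets, interferon-stimulated genes and hypoxia genes were mostly higher in Q-BCSC, and the cell cycle inhibitor CDKN1A (ENSG00000124762; chromosome 6, 36676460 to 36687339) was 4.56-fold higher there. Transcripts of T lymphocytes were counted in every Q-BCSC library. NANOG (ENSG00000111704; chromosome 12, 7787794 to 7799141), the pluripotency factor whose reporter was sorted on, lay at 33.1 ± 2.40 CPM in A-BCSC and 29.9 ± 1.39 in Q-BCSC and did not pass the test (edgeR adjusted p = 0.183). Near-identical processed copies make its level uncertain, and whether reads of a reporter could count toward it was not measured.

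Cell cycle genes moved together. Of 46 genes of DNA replication and G1/S, 44 were higher in A-BCSC, 0 lower and 2 not past the threshold (45 higher adjusted over the list alone), with a median log2 fold change of 0.95 (camera adjusted p = 4.28e-45). CDC6, which licenses replication origins, rose by 1.45 ± 0.0678 (SE) on the log2 scale from 46.0 to 125.2 CPM, and the flap endonuclease FEN1 rose from 119.9 to 286.9 CPM. Of 44 genes of G2/M and mitosis, 43 were higher, 0 lower and 1 not past (the same numbers adjusted over the list alone), with a median of 0.68 (camera adjusted p = 2.96e-30). TOP2A, the DNA topoisomerase of dividing cells, rose from 387.1 to 827.1 CPM, and TPX2, a spindle assembly factor, from 254.0 to 528.4 CPM. The proliferation marker MKI67 lay at 484.8 ± 21.3 CPM in A-BCSC and 314.7 ± 18.4 in Q-BCSC (log2 0.62 ± 0.0594, edgeR adjusted p = 1.36e-07). The inhibitors CDKN1A (log2 -2.19 ± 0.0760, edgeR adjusted p = 1.75e-13) and CDKN1B (log2 -1.21 ± 0.0623, edgeR adjusted p = 3.58e-11) were lower in A-BCSC. The wider list of quiescence and dormancy genes split: of 27, 6 were higher, 11 lower and 10 not past (the same adjusted over the list alone), with a median of -0.19 that camera did not call (adjusted p = 0.123). Its members BHLHE40 (375.6 to 147.7 CPM) and the thioredoxin inhibitor TXNIP (log2 -1.45) fell, while NR2F1 (log2 1.79), TGFB2 (log2 1.82) and SOX9 (43.8 to 100.9 CPM), known from dormancy and stem cell studies, rose.

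Metabolic genes differed as well. All 13 mitochondrially encoded protein genes were higher in A-BCSC, 13 also adjusted over the list alone, with a median of 1.54 (camera adjusted p = 9.43e-42). MT-ND4, a subunit of respiratory complex I, rose from 2297 ± 132 to 8991 ± 192 CPM, and MT-CO3, a subunit of complex IV, from 1866 to 6675 CPM. Of 12 genes of serine and one-carbon synthesis, 9 were higher, 0 lower and 3 not past (9 adjusted over the list alone; median 0.65, camera adjusted p = 1.35e-08), among them PHGDH, which starts serine synthesis (18.6 to 48.1 CPM), and PSAT1 (87.0 to 211.5 CPM). ATF4 and amino acid response genes rose in 17 of 29 cases and fell in 5, with 7 not past (17 and 5 adjusted over the list alone; median 0.50, camera adjusted p = 3.18e-06); the amino acid transporter SLC7A5 went from 123.6 to 230.3 CPM. Of 21 genes of the TCA cycle and pyruvate dehydrogenase, 14 were higher, 0 lower and 7 not past (15 higher adjusted over the list alone; median 0.25, camera adjusted p = 0.00597), but adjusted p = 0.0772 with an estimated correlation. For 62 nuclear genes of oxidative phosphorylation, 27 were higher, 2 lower and 33 not past (30 and 2 adjusted over the list alone; median 0.185, camera adjusted p = 0.00173), with adjusted p = 0.394 with an estimated correlation. The ATP synthase subunit ATP5F1A (log2 0.50) and the citric acid cycle enzymes SDHA (log2 0.39) and FH (log2 0.41) were examples. Of 24 glycolysis genes, 3 were higher, among them ENO1, 9 lower and 12 not past (the same adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.000386, and adjusted p = 0.331 with an estimated correlation). The glucose transporter SLC2A3 fell from 264.5 to 52.4 CPM, hexokinase HK2 from 253.8 to 115.1 and ENO2 from 244.9 to 117.2. Mitochondrial counts took a larger share of A-BCSC than of Q-BCSC libraries, as given above.

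Camera called the targets of the transcriptional coactivator YAP and of TGF-beta higher in A-BCSC as lists. Of 22 YAP targets, 13 rose, 3 fell and 6 did not pass (the same adjusted over the list alone), with a median of 0.32 (camera adjusted p = 9.97e-24). ANKRD1 (ENSG00000148677; chromosome 10, 90912096 to 90921276) rose 7.89-fold from 52.0 ± 1.40 to 410.0 ± 19.1 CPM, the matricellular protein CTGF from 79.1 to 494.9 CPM, and CYR61 from 472.7 to 1908 CPM. Of 12 TGF-beta targets, which share CTGF and TGFB2 with that list, 6 rose, 3 fell and 3 did not pass (the same adjusted over the list alone; median 0.36, camera adjusted p = 4.13e-05). Epithelial genes were higher in 8 of 16 cases, with 0 lower and 8 not past (10 higher adjusted over the list alone; median 0.59, camera adjusted p = 0.00053, and adjusted p = 0.163 with an estimated correlation); keratin KRT7 went from 220.0 to 630.7 CPM. Mesenchymal genes split into 6 higher, 10 lower and 6 not past of 22 (the same adjusted over the list alone; median -0.18, camera adjusted p = 0.0107, and adjusted p = 0.25 with an estimated correlation). The collagen cross-linker LOX fell from 99.7 to 25.5 CPM.

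Immediate early genes were lower in A-BCSC than in Q-BCSC, as were most NF-kB targets, interferon-stimulated genes and hypoxia genes. All 17 immediate early genes fell (17 also adjusted over the list alone; median -1.53, camera adjusted p = 2.83e-50), with FOS from 141.6 to 8.51 CPM and EGR1 from 130.7 to 9.10 CPM. Of 24 NF-kB targets and cytokines, 22 fell, 1 rose and 1 did not pass (the same adjusted over the list alone; median -2.17, camera adjusted p = 3.77e-37). The prostaglandin synthase PTGS2 fell from 68.8 to 4.30 CPM and the adhesion molecule ICAM1 from 95.6 to 9.78 CPM, while the cytokine IL11 rose (log2 1.42). Interferon-stimulated genes fell in 28 of 34 cases, with 2 higher and 4 not past (the same adjusted over the list alone; median -1.04, camera adjusted p = 3.25e-21). DDX60 went from 99.0 to 22.2 CPM and IFIT3 from 235.1 to 81.5 CPM, and the exceptions were OAS1 (16.7 to 38.4 CPM) and IFIT5 (log2 0.42). Of 22 hypoxia genes, 15 fell, 3 rose and 4 did not pass (17 and 4 adjusted over the list alone; median -0.52, camera adjusted p = 9.36e-10), with the angiogenic factor VEGFA from 310.8 to 77.3 CPM and NDRG1 from 416.3 to 157.2 CPM. The Q-BCSC libraries that were higher in these groups also held lymphocyte transcripts. Genes of the fixed blood cell list had 676, 731 and 609 counts in Q-BCSC replicates 1, 2 and 3 and 27, 36 and 15 in A-BCSC. Of its 5 tested members 4 were lower in A-BCSC and 0 higher (the same adjusted over the list alone; median -6.06 with genes at 0 set to their bound, camera adjusted p = 8.31e-08). Over genes with at least 1 CPM in siNC or EGFP-negative, chosen after seeing the data, all 7 other lists lower in A-BCSC were still called. This does not show that they are free of lymphocyte reads, since these genes include ones that lymphocytes express too.

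The largest single changes came from several kinds of gene. Among the rises, the gel-forming mucin MUC5AC (ENSG00000215182; chromosome 11, 1157953 to 1201138) went from 38.9 ± 3.72 to 546 ± 69.5 CPM, a fold of 14.0 (edgeR adjusted p = 1.42e-15). The vasoconstrictor peptide EDN1 rose from 1.98 to 20.99 CPM and the aryl hydrocarbon receptor target CYP1A1 from 0.787 to 8.23 CPM. CAPN8 (log2 4.36), RAB17 (log2 3.69) and SORBS2 (log2 3.09) rose as well. BOLA2B (log2 4.96), XAGE1B (log2 4.76) and ALPP (log2 4.29) are uncertain, because near-identical copies can share their reads; BOLA2B rested on A-BCSC replicate 1, without which its log2 change was 0.25 (edgeR adjusted p = 0.754), and limma-voom did not call it (adjusted p = 0.256). Among the falls, the immediate early gene FOSB (ENSG00000125740; chromosome 19, 45467995 to 45475179) went from 238.4 ± 11.6 to 0.774 ± 0.120 CPM, a fold of 306.2 (edgeR adjusted p = 7.38e-20). The histone gene HIST1H2BB (ENSG00000276410; chromosome 6, 26043277 to 26043657) went from 761.8 ± 48.0 to 13.6 ± 0.237 CPM, a fold of 55.8. The other 8 were immune genes. PTPRC (ENSG00000081237; chromosome 1, 198638457 to 198757476), which encodes the leukocyte antigen CD45, had 1148 counts in Q-BCSC and 0 in A-BCSC, at least 360-fold lower. DOCK8 was at least 197-fold lower (0 against 629 counts) and the integrin ITGAL at least 183-fold lower (0 against 582 counts). The granzyme GZMA had 1 count against 955, a ratio of 900 (counting interval 161 to 35600). LTB (log2 -6.42), GZMB (log2 -6.14), IL32 (log2 -6.11) and BCL2A1 (log2 -5.65) completed the list. IL32 is also on the fixed NF-kB list. In the reporter sort, BCL2A1 lay at 14.6 to 16.4 CPM in EGFP-positive libraries and at most 0.155 in EGFP-negative ones. PTPRC lay at only 0.441 to 0.564 CPM in the same EGFP-positive libraries, so BCL2A1 alone does not mark lymphocyte reads.

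Stemness genes showed no common direction. The surface marker CD44 was lower in A-BCSC, at 370.6 ± 9.50 against 658.3 ± 10.9 CPM (log2 -0.83, edgeR adjusted p = 6.07e-10). ALDH1A3 (log2 -0.30, edgeR adjusted p = 0.218) did not pass, and SOX2, with 8 counts in A-BCSC and 6 in Q-BCSC, was too low to test. MYC was slightly higher (log2 0.21, edgeR adjusted p = 0.0435). POU5F1 was higher too (log2 1.495, edgeR adjusted p = 0.0279), on 65 against 24 counts and with near-identical pseudogene copies. Both calls rest on few libraries. MYC had adjusted p = 0.153 without Q-BCSC replicate 1, 0.0679 without Q-BCSC replicate 3, 0.12 without A-BCSC replicate 1 and 0.0878 without A-BCSC replicate 3, and 0.162 with upper-quartile scaling, 0.0771 with the strict filter, 0.079 with the block and 0.105 over genes of at least 1 CPM in siNC or EGFP-negative. POU5F1 had adjusted p = 0.0684 without Q-BCSC replicate 1, 0.116 without Q-BCSC replicate 2, 0.095 without A-BCSC replicate 1, 0.105 without A-BCSC replicate 3 and 0.0695 in the DESeq2 Wald test. Of 18 breast cancer stem cell markers 8 rose, 3 fell and 7 did not pass (9 and 3 adjusted over the list alone), with a median of 0.175, a mean of -0.193 and no call by camera (upward, adjusted p = 0.18). The drug exporter ABCG2 rose from 9.91 to 20.6 CPM and SOX9 from 43.8 to 100.9 CPM, while the chemokine receptor CXCR4 fell. Of 7 pluripotency genes 3 rose, 1 fell and 3 did not pass (4 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.849).

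Of 17930 genes tested with edgeR, 3963 were higher and 3861 lower in A-BCSC, which is 43.6% of them; at a fold of at least 2 the counts were 468 and 1466. Over genes of at least 1 CPM in siNC or EGFP-negative, chosen after seeing the data, 3309 were higher and 3382 lower. With upper-quartile scaling 3072 were higher and 4515 lower, so the higher share of calls went from 50.7% to 40.5%. Camera called 14 of 33 lists higher and 8 lower; 13 of these 22 held with an estimated correlation.

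**Figure D1:**
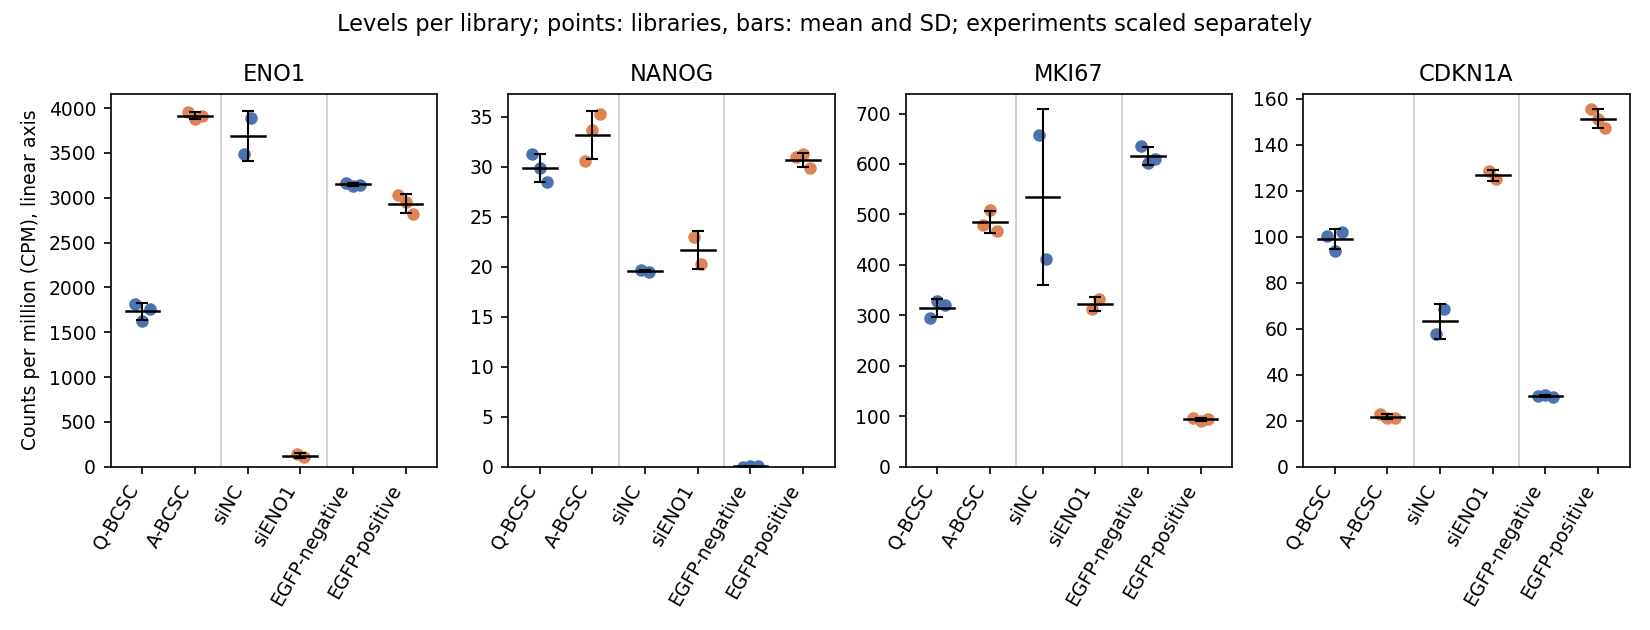
Levels of ENO1, NANOG, MKI67 and CDKN1A in CPM (linear axes) for each library of the 6 groups, with bars for the mean and SD; the 3 experiments were scaled separately, so levels compare only within an experiment. ENO1 lay at 3918 CPM in A-BCSC against 1733 in Q-BCSC and at 125.1 in siENO1 against 3688 in siNC, while NANOG lay at 30.7 CPM in EGFP-positive against 0.0261 in EGFP-negative.

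The silencing experiment asked what follows the loss of ENO1 in unsorted cells. No other siRNA against ENO1 and no rescue is among the groups. Effects of ENO1 loss and other effects of the siRNA thus cannot be told apart. ENO1 (ENSG00000074800; GRCh38 chromosome 1, release 110) fell in both siENO1 libraries, to 144.8 and 105.4 CPM from 3488 and 3887 CPM in the siNC libraries, a fold of 29.5 (log2 -4.88 ± 0.220, edgeR adjusted p = 1.29e-11). Camera called the lists of cell cycle genes and stem cell markers lower in siENO1, and those of ATF4, NF-kB and NRF2 targets higher. Many of their members did not pass, and no list call in this experiment held with an estimated correlation. With 2 libraries per group that setting has few residual degrees of freedom and little power, so a lost call alone does not show correlated members. For NF-kB targets the estimated correlation was -0.0438, below the preset of 0.01, and the call was lost all the same. Stem cell markers (-0.0114), immediate early genes (-0.0486) and histones (-0.0744) also lay below it. The other called lists lay above it, from 0.0175 for G2/M and mitosis to 0.307 for heat shock. For those the preset may understate the correlation. CDKN1A rose from 63.3 ± 7.66 to 126.8 ± 2.51 CPM (log2 1.00 ± 0.158, edgeR adjusted p = 0.000248). NANOG lay at 21.6 ± 1.89 CPM in siENO1 and 19.6 ± 0.0838 in siNC and did not pass (edgeR adjusted p = 0.641).

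Of 46 genes of DNA replication and G1/S, 17 fell, 1 rose and 28 did not pass (24 and 1 adjusted over the list alone; median -0.38, camera adjusted p = 7.92e-10, and adjusted p = 0.349 with an estimated correlation). The replicative helicase subunit MCM6 fell from 195.6 to 96.3 CPM (edgeR adjusted p = 0.000145). G2/M and mitosis genes fell in 17 of 42 cases, with 0 higher and 25 not past (25 lower adjusted over the list alone; median -0.42, camera adjusted p = 2.82e-10, and adjusted p = 0.349 with an estimated correlation). TOP2A went from 735.2 to 319.7 CPM (edgeR adjusted p = 5.61e-05). MKI67 lay at 322.8 ± 13.3 CPM against 534.4 ± 174 (log2 -0.73, edgeR adjusted p = 0.0141), a call that rests on siNC replicate 1: without it the log2 change was -0.35 (adjusted p = 0.402). CDKN1B (log2 0.23, adjusted p = 0.401) did not pass. Of 27 quiescence and dormancy genes 5 rose, 6 fell and 16 did not pass (5 and 8 adjusted over the list alone; median -0.11, camera adjusted p = 0.275), with KLF2 (log2 -1.18) and CCNG2 (log2 -1.19) among those that fell.

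Stem cell markers fell in 8 of 16 cases, with 1 higher and 7 not past (the same adjusted over the list alone; median -0.50, camera adjusted p = 0.000101, and adjusted p = 0.349 with an estimated correlation). SOX9 fell from 114.2 to 40.2 CPM (edgeR adjusted p = 1.96e-05), the intermediate filament NES from 18.8 to 5.33 CPM and the protein C receptor PROCR from 44.4 to 22.3 CPM. CD44 went from 531.7 ± 37.0 to 375.1 ± 22.7 CPM (log2 -0.50, edgeR adjusted p = 0.0402), but its adjusted p was 0.275 without siNC replicate 1, 0.132 without siNC replicate 2, 0.118 without siENO1 replicate 1, 0.0532 with upper-quartile scaling and 0.123 with the block. ALDH1A3 (log2 -0.205, adjusted p = 0.79) and MYC (log2 -0.11, adjusted p = 0.684) did not pass. POU5F1 (11 counts in siENO1, 5 in siNC) and SOX2 (0 and 1) were too low to test. Of 6 pluripotency genes 1 fell, 0 rose and 5 did not pass (the same adjusted over the list alone), with a median of 0.11, a mean of -0.10 and no call (camera downward, adjusted p = 0.627).

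ATF4 and amino acid response genes rose in 13 of 28 cases, with 0 lower and 15 not past (16 higher adjusted over the list alone; median 0.495, camera adjusted p = 2.74e-07, and adjusted p = 0.487 with an estimated correlation). The stress sensor SESN2 rose from 25.7 to 90.4 CPM (edgeR adjusted p = 5.27e-07), the transcription factor ATF3 from 19.9 to 41.5 CPM, and TRIB3 from 49.7 to 84.6 CPM, the last with adjusted p = 0.0703 without siNC replicate 1. Of 23 NF-kB targets and cytokines 12 rose, 0 fell and 11 did not pass (15 higher adjusted over the list alone; median 0.77, camera adjusted p = 2.82e-10, and adjusted p = 0.349 with an estimated correlation), among them the apoptosis inhibitor BIRC3 (26.1 to 64.8 CPM) and TNFAIP3 (48.8 to 103.9 CPM). Of 16 NRF2 targets 7 rose, 1 fell and 8 did not pass (10 and 1 adjusted over the list alone; median 0.575, camera adjusted p = 0.00024, and adjusted p = 0.504 with an estimated correlation). AKR1B10 (log2 2.75) and OSGIN1 (log2 1.30) rose. Immediate early genes (4 of 15 higher, 0 lower, 11 not past, the same adjusted over the list alone; median 0.21) were called by camera (adjusted p = 0.0244, and adjusted p = 0.487 with an estimated correlation), but not without siNC replicate 1 (0.0938) or siENO1 replicate 1 (0.0512). Interferon-stimulated genes (7 of 31 higher, 5 lower and 19 not past, with 11 and 6 adjusted over the list alone; median 0.18) were not called (camera adjusted p = 0.0664), except without siENO1 replicate 2 (0.0446).

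Few metabolic genes passed. Glycolysis genes other than ENO1 rose in 3 of 23 cases, with 0 lower and 20 not past (the same adjusted over the list alone; median 0.20, camera adjusted p = 0.0244, and adjusted p = 0.571 with an estimated correlation), and the call was lost without siNC replicate 1 (0.0938) or siENO1 replicate 1 (0.132). All 3 encode transporters: SLC2A3 rose from 31.4 to 88.1 CPM (edgeR adjusted p = 6.84e-06), SLC2A1 from 306.2 to 481.0 CPM (adjusted p = 0.00855; 0.0619 without siNC replicate 1 and 0.122 without siNC replicate 2), and SLC16A1 had log2 1.07 (adjusted p = 0.026; 0.356 without siNC replicate 2 and 0.127 in the DESeq2 Wald test). Camera did not call the TCA cycle list (0 higher, 2 lower, 19 not past of 21, the same adjusted over the list alone; median -0.12, adjusted p = 0.276), nuclear oxidative phosphorylation (1 higher, 3 lower, 58 not past of 62, the same adjusted over the list alone; median -0.10, adjusted p = 0.112, but 0.000658 without siNC replicate 1 and 1.97e-05 without siENO1 replicate 1) or serine synthesis (0 of 12 past, also adjusted over the list alone; median 0.0133, adjusted p = 0.896). The mitochondrially encoded list had 1 of 13 higher and 0 lower (the same adjusted over the list alone), with a median of -0.0071 that turned to 0.0138 with upper-quartile scaling, a mean of 0.0418 and no call (camera upward, adjusted p = 0.96). Hypoxia genes rose in 5 of 22 cases, with 2 lower and 15 not past (7 and 2 adjusted over the list alone; median 0.12, camera adjusted p = 0.0884).

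Among the largest rises, ABCC9 (ENSG00000069431; GRCh38 chromosome 12, 21797389 to 21942543), the regulatory subunit of a potassium channel, went from 7.85 ± 0.935 to 54.3 ± 6.29 CPM, a fold of 6.93 (edgeR adjusted p = 1.64e-08). INHBA, an activin subunit, rose from 0.999 to 6.36 CPM and the chemokine CCL20 from 1.499 to 6.73 CPM. CEACAM19 (log2 2.27), NEK10 (log2 2.11), DNAH1 (log2 2.00) and LAMA1 (log2 1.99) rose as well, and NBPF10, NBPF14 and NBPF26 (log2 2.04 to 2.26) belong to a family of near-identical copies and are uncertain. Among the falls after ENO1, the lysosomal acid lipase LIPA (ENSG00000107798; chromosome 10, 89213569 to 89414557) went from 63.0 ± 0.639 to 12.9 ± 0.441 CPM, a fold of 4.88 (edgeR adjusted p = 7.44e-08), INSIG1, a regulator of sterol synthesis, from 71.6 to 16.5 CPM, and the collagen COL8A1 from 9.76 to 1.42 CPM. LHPP (log2 -2.57), SHISAL1 (log2 -2.45), SHISA3 (log2 -2.11), GPRASP2 (log2 -2.11), SOX21 (log2 -2.025) and KIF3C (log2 -2.02) fell too.

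Of 14904 genes tested with edgeR, 1042 were higher and 1144 lower in siENO1, which is 14.7% of them. Without siNC replicate 2 these counts were 389 and 558, and in the DESeq2 Wald test 669 genes were higher. Camera called 8 of 32 lists higher and 6 lower.

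The reporter sort asked how cells with the NANOG reporter differ from cells without it. NANOG itself had 2208 counts in EGFP-positive and 2 in EGFP-negative libraries, a ratio of 1140 (counting interval 314 to 9400), with 30.7 ± 0.710 CPM in EGFP-positive. Its copies leave the level uncertain, and whether reads of a reporter could count toward it was not measured. All hypoxia genes and most NF-kB targets, interferon-stimulated genes and quiescence genes were higher in EGFP-positive cells, and all genes of the cell cycle and heat shock lists and most of the TCA cycle list were lower. MKI67 was lower, at 93.6 ± 2.72 against 615.6 ± 17.4 CPM (log2 -2.72 ± 0.0340, edgeR adjusted p = 2.17e-40), and CDKN1A was 4.93-fold higher, at 151.4 ± 4.22 against 30.7 ± 0.524 CPM. ENO1 barely differed, at 2936 ± 111 against 3150 ± 17.2 CPM (log2 -0.10 ± 0.0275, edgeR adjusted p = 0.00107), and its sign turned with upper-quartile scaling (log2 0.10, adjusted p = 0.00134). That scaling moved the median log2 fold change of all genes by 0.203.

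All 46 genes of DNA replication and G1/S (median -2.66, camera adjusted p = 1.14e-53) and all 44 of G2/M and mitosis (median -2.60, camera adjusted p = 2.33e-59) were lower in EGFP-positive cells, 46 and 44 also adjusted over the list alone. The helicase subunit MCM4 fell from 353.2 to 39.7 CPM, UHRF1, a maintenance factor of DNA methylation, from 240.3 to 19.2 CPM, and TOP2A from 1118 to 162.8 CPM. Quiescence and dormancy genes rose in 20 of 28 cases, with 4 lower and 4 not past (the same adjusted over the list alone; median 0.96, camera adjusted p = 6.48e-08). TXNIP went from 27.6 to 1226 CPM, BHLHE40 from 120.6 to 946.3 CPM and the mTOR inhibitor DDIT4 from 30.2 to 235.7 CPM. CDKN1B rose less (log2 0.40, edgeR adjusted p = 3.84e-09). All 14 heat shock genes fell (14 adjusted over the list alone; median -1.86, camera adjusted p = 1.64e-16), with the chaperone HSPA8 from 3267 to 749.2 CPM.

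All 22 hypoxia genes rose (22 adjusted over the list alone; median 2.26, camera adjusted p = 4.46e-49). NDRG1 (ENSG00000104419; GRCh38 chromosome 8, 133237171 to 133302022), a hypoxia-induced gene, went from 89.0 ± 1.57 to 4670 ± 41.4 CPM, a fold of 52.4, and VEGFA from 76.3 to 1119 CPM. Of 24 NF-kB targets and cytokines 23 rose and 1 fell (the same adjusted over the list alone; median 4.52, camera adjusted p = 4.54e-38), with ICAM1 from 2.87 to 299.6 CPM, TNFAIP3 from 14.8 to 412.4 CPM, and IL11 as the exception (log2 -1.02). Of 35 interferon-stimulated genes 32 rose and 3 fell (the same adjusted over the list alone; median 2.93, camera adjusted p = 6.85e-34), with DDX60 from 19.7 to 985.1 CPM and IFIT2 from 41.2 to 482.9 CPM. All 17 immediate early genes rose (17 adjusted over the list alone; median 2.65, camera adjusted p = 3.18e-14), such as EGR1 (22.4 to 328.4 CPM) and JUNB (24.9 to 264.0 CPM). The fixed blood cell list had 2 tested members here, and neither passed, also adjusted over the list alone; PTPRC, chosen after its values were seen, lay at 0.516 CPM in EGFP-positive and 0.7001 in EGFP-negative (edgeR adjusted p = 0.34).

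Energy metabolism genes split by pathway. Glycolysis genes rose in 15 of 24 cases, fell in 6 and did not pass in 3 (the same adjusted over the list alone; median 0.61, camera adjusted p = 1.11e-08, and adjusted p = 0.141 with an estimated correlation). With upper-quartile scaling 20 rose and 3 fell. SLC2A3 went from 36.6 to 709.2 CPM, ENO2 from 70.8 to 654.9 CPM and the aldolase ALDOC from 44.7 to 438.9 CPM, while LDHB (log2 -1.46) and PGAM1 (log2 -0.56) fell. Of 21 genes of the TCA cycle and pyruvate dehydrogenase 18 fell, 2 rose and 1 did not pass (the same adjusted over the list alone; median -0.95, camera adjusted p = 1.9e-07), with citrate synthase CS from 344.5 to 139.2 CPM. Of 62 nuclear genes of oxidative phosphorylation 59 fell, 2 rose and 1 did not pass (the same adjusted over the list alone; median -0.99, camera adjusted p = 3.2e-11, and adjusted p = 0.125 with an estimated correlation), with ATP5PB from 403.7 to 120.9 CPM. The mitochondrially encoded genes were mixed, 4 higher, 7 lower and 2 not past of 13 (the same adjusted over the list alone; 6 and 6 with upper-quartile scaling), with a median of -0.18 that turned to 0.0241 with upper-quartile scaling (camera adjusted p = 0.586). Of 12 serine and one-carbon genes 4 rose and 8 fell (the same adjusted over the list alone), with a median of -0.545; camera did not call them (adjusted p = 0.0702), except without EGFP-negative replicate 1 (0.0455). ATF4 and amino acid response genes (15 higher, 9 lower, 4 not past of 28, the same adjusted over the list alone; median 0.30) were not called (camera adjusted p = 0.0832).

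YAP targets went both ways: of 22, 9 rose, 10 fell and 3 did not pass (9 and 11 adjusted over the list alone; 12 and 10 with upper-quartile scaling). Their median of -0.0451 turned to 0.158 with upper-quartile scaling, and camera's call (downward, adjusted p = 0.0303) was lost without EGFP-positive replicate 2 (0.0638) and had adjusted p = 0.187 with an estimated correlation. ANKRD1 fell 93.2-fold, from 412.4 ± 3.28 to 4.41 ± 0.379 CPM, CYR61 from 1826 to 208.6 CPM and CTGF from 344.6 to 45.5 CPM, while the growth factor binding protein IGFBP3 (log2 7.79) and tissue factor F3 (log2 1.93) rose. TGF-beta targets (8 higher, 3 lower, 1 not past of 12, the same adjusted over the list alone; median 0.70) were not called (camera adjusted p = 0.9). Mesenchymal genes rose in 16 of 22 cases, with 4 lower and 2 not past (the same adjusted over the list alone; median 0.48, camera adjusted p = 3.91e-05, and adjusted p = 0.0829 with an estimated correlation), among them LOX (18.8 to 1789 CPM) and fibronectin FN1 (345.6 to 2310 CPM). Epithelial genes had 11 higher, 5 lower and 1 not past of 17 (the same adjusted over the list alone), with a median of 0.58 and a mean of 0.87, yet camera's direction was downward (adjusted p = 0.947); KRT7 fell from 556.9 to 78.0 CPM. CD44 rose (log2 0.43, edgeR adjusted p = 2.55e-16) and MYC fell (log2 -0.45, edgeR adjusted p = 1.33e-08). ALDH1A3 rose (log2 0.49, adjusted p = 0.0118), but not without EGFP-negative replicate 2 (0.0845), without EGFP-positive replicate 3 (0.0661) or in the DESeq2 Wald test (0.0778). POU5F1 (log2 0.53, adjusted p = 0.34) did not pass, and SOX2 (9 against 3 counts) was not tested. Stem cell markers (9 higher, 5 lower, 2 not past of 16, the same adjusted over the list alone; median 0.42, camera adjusted p = 0.409) were not called. Neither were the 7 pluripotency genes (2 higher, 3 lower, 2 not past, the same adjusted over the list alone), whose median of -0.0109 turned to 0.0118 with DESeq2 size factors and 0.192 with upper-quartile scaling beside a mean of 1.60 (camera upward, adjusted p = 0.058).

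The largest rise was in ACKR3 (ENSG00000144476; GRCh38 chromosome 2, 236567787 to 236582358), an atypical chemokine receptor, with 5654 counts in EGFP-positive and 1 in EGFP-negative libraries, a ratio of 5820 (counting interval 1040 to 230000). CH25H, which makes 25-hydroxycholesterol, had 1063 against 1 (1090, interval 196 to 43300). SERPING1 was at least 138-fold higher (402 against 0 counts) and PTPRN2 at least 133-fold higher (386 against 0). The receptor TREM1 (0.0538 to 109.9 CPM), TNFAIP6 (0.0554 to 53.2 CPM), the growth factor PDGFB (0.0517 to 50.8 CPM), NDUFA4L2 (0.138 to 119.0 CPM) and CCL20 (0.120 to 88.0 CPM) rose as well. Among the falls, the cadherin CDH19 had 2 counts against 716 (348, interval 95.9 to 2880), and SPANXB1, which has near-identical copies and is uncertain, had 1 against 541 (525, interval 93.9 to 20800). After ANKRD1 came CDK15 (log2 -5.49), SHISA3 (284.9 to 9.03 CPM), ID3, an inhibitor of basic helix-loop-helix factors (80.4 to 3.13 CPM), ZNF486 (log2 -4.67), ZNF85 (log2 -4.55), CENPM (log2 -4.47) and BMP5 (log2 -4.38).

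Of 17126 genes tested with edgeR, 7009 were higher and 6922 lower in EGFP-positive cells, which is 81.3% of them; at a fold of at least 2 the counts were 3836 and 2796. With upper-quartile scaling 8253 were higher and 5702 lower, so the higher share of calls went from 50.3% to 59.1%. Camera called 10 of 32 lists higher and 7 lower, and 9 of these 17 held with an estimated correlation. The spread between these libraries was small (common dispersion 0.0012, against 0.00845 in the state sort and 0.0163 in the silencing experiment), and it may be technical.

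**Figure D2:**
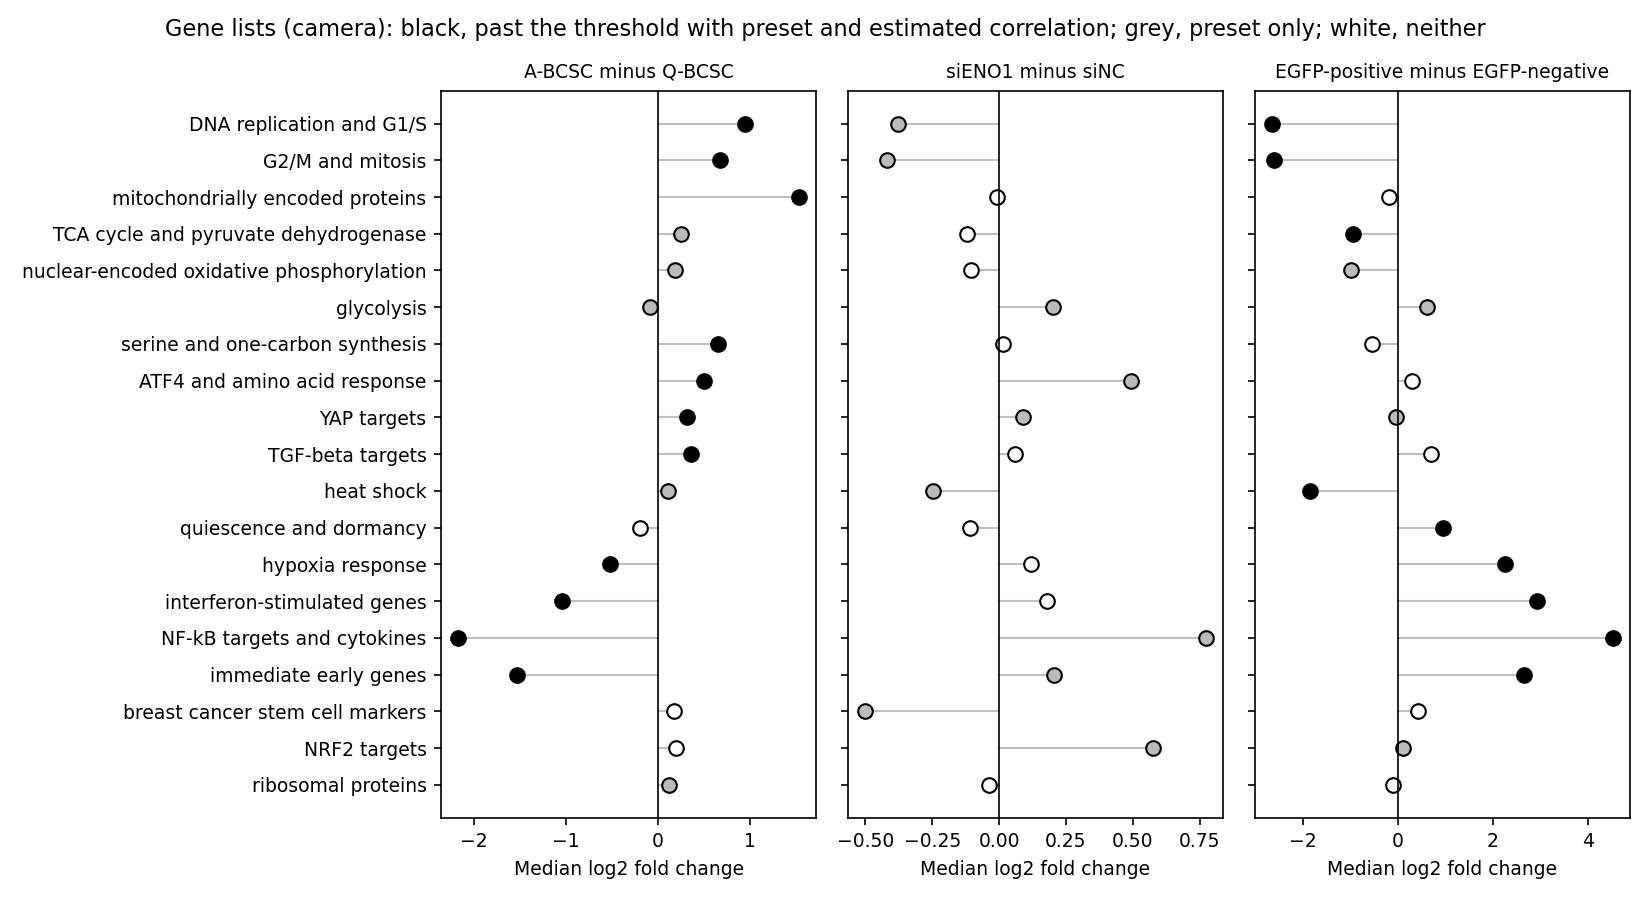
Median log2 fold change of 19 gene lists in the 3 comparisons (x axes differ between panels), with black points past the camera threshold with the preset and the estimated correlation, grey points with the preset only and white points with neither. Cell cycle lists lay above 0 in A-BCSC (0.95 and 0.68) and below 0 in EGFP-positive cells (-2.66 and -2.60); with upper-quartile scaling the sign turned for mitochondrially encoded proteins in siENO1 and EGFP-positive and for YAP targets and ribosomal proteins in EGFP-positive.

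Both the state sort and the reporter sort used NANOG-EGFP, the former together with H2B-mCherry, and their changes were set against each other. Genes higher in A-BCSC tended to be lower in EGFP-positive cells. Across 16451 genes tested in both, which are not independent, the log2 fold changes had r = -0.532 and rho = -0.552. Of the genes past the threshold in both, 3006 were higher in A-BCSC and lower in EGFP-positive (1639 expected for independent lists), and 2643 were lower in A-BCSC and higher in EGFP-positive (1386 expected). Both rose for 580 genes (1549 expected) and both fell for 388 (1466 expected). The 200 rising genes of the state sort fell in EGFP-positive cells (median -1.33, camera adjusted p = 2.54e-34), and its 200 falling genes rose there (median 2.19, camera adjusted p = 1.12e-98). ANKRD1, CYR61, TOP2A and CDC6 belong to the rising side of the state sort, and FOS, PTGS2, VEGFA and CDKN1A to the falling side.

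**Figure D3:**
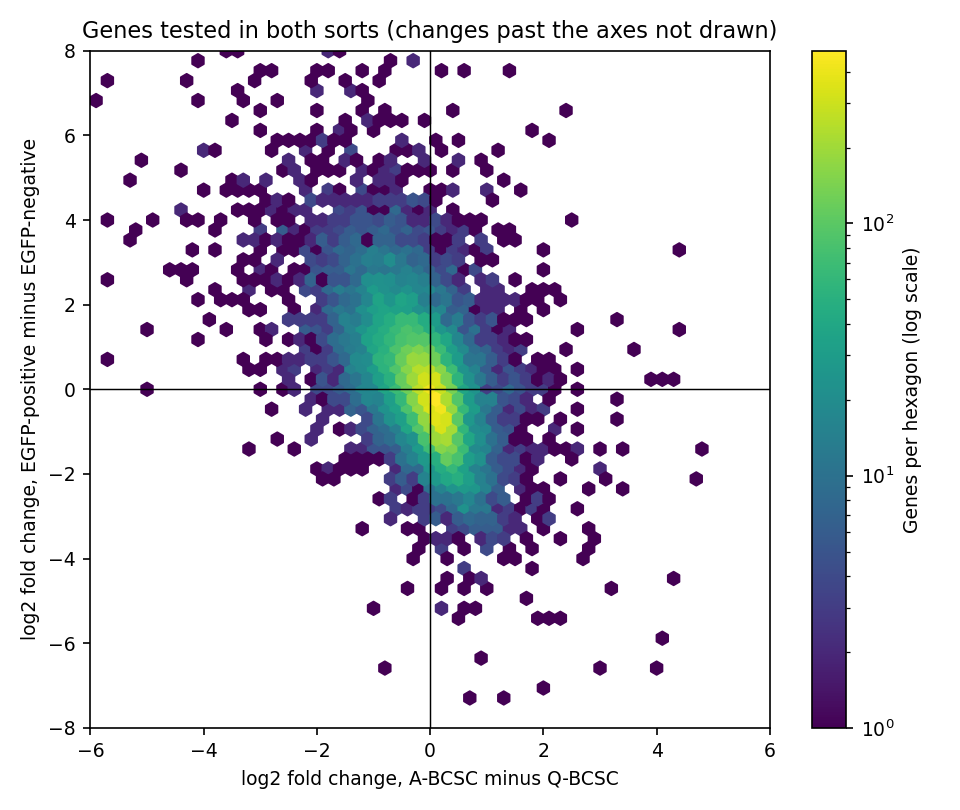
Log2 fold change of each gene in the state sort (x axis, A-BCSC minus Q-BCSC) against the reporter sort (y axis, EGFP-positive minus EGFP-negative), with hexagons shaded by the number of genes on a log scale. The 16451 genes lie along a falling diagonal (r = -0.532); 37 genes past the axis limits of 6 and 8 are not drawn.

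Genes higher in A-BCSC tended to be lower after silencing of ENO1 as well. Across 14246 genes tested in both, r was -0.333 and rho -0.319. Calls were higher in A-BCSC and lower in siENO1 for 560 genes (301 expected), lower and higher for 533 (208 expected), higher in both for 87 (262 expected) and lower in both for 120 (239 expected). The 200 rising genes of the state sort fell in siENO1 (median -0.33, camera adjusted p = 4.53e-13). Its 200 falling genes rose (median 0.325, camera adjusted p = 2.86e-12, and adjusted p = 0.0638 with an estimated correlation). Between the reporter sort and silencing, r was 0.216 and rho 0.215 across 14136 genes. Calls were higher in both for 629 genes (383 expected), lower in both for 669 (515 expected), and opposite for 345 (434 expected) and 222 (454 expected). The 200 rising genes of the reporter sort rose in siENO1 (median 0.28, camera adjusted p = 4.47e-08) and its 200 falling genes fell (median -0.295, camera adjusted p = 2.22e-12), each with adjusted p = 0.0823 with an estimated correlation.

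Lymphocyte genes were examined further after PTPRC had been seen among the largest falls in A-BCSC. The T cell receptor complex genes CD3D (0 counts in A-BCSC, 213 in Q-BCSC, at least 66.9-fold lower) and CD3E (0 and 414, at least 130-fold lower) were lower in A-BCSC, as were perforin PRF1 (0 and 330, at least 104-fold lower), TRAC (63 and 673 counts, log2 -3.33) and CD8A (85 and 909 counts, log2 -3.32). In Q-BCSC, PTPRC lay at 10.6 ± 1.24 CPM and CD8A at 8.37 ± 0.661. The B cell gene MS4A1 and the haemoglobin gene HBB had 0 counts in both groups, and the monocyte marker CD14 (33 and 53 counts, edgeR adjusted p = 0.399) did not pass. Of 106 T cell receptor V segments in the annotation, the Q-BCSC libraries had a count in 53, 55 and 61 and the A-BCSC libraries in 5, 10 and 10.

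**Figure D4:**
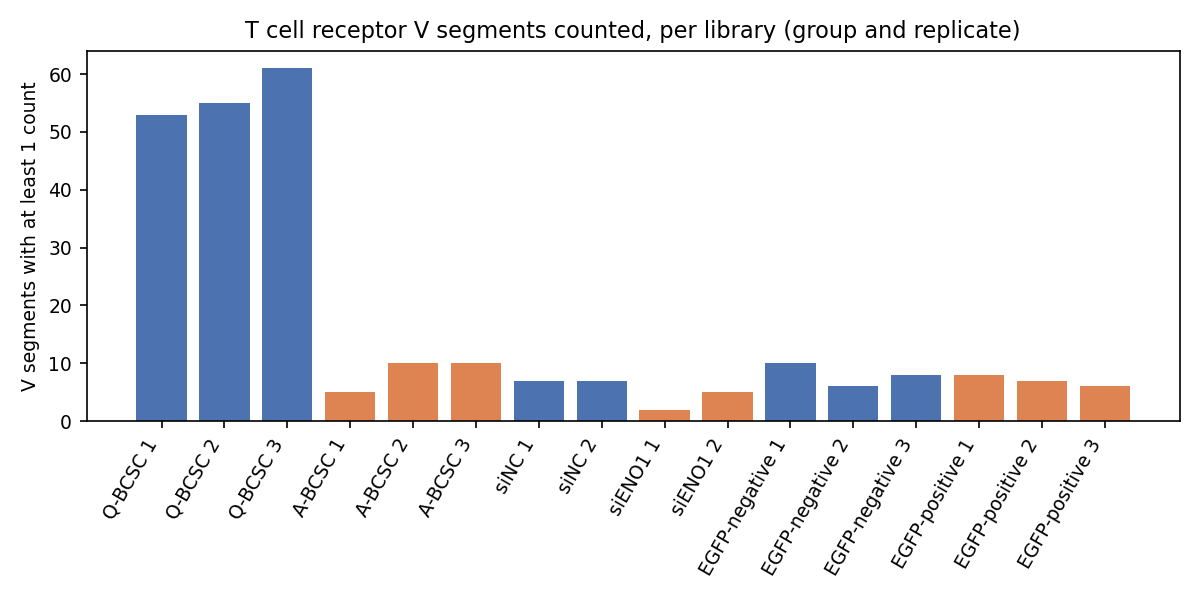
Number of T cell receptor V segments with at least 1 count (y axis) in each library (x axis, group and replicate), with each bar starting at 0. The 3 Q-BCSC libraries have 53, 55 and 61, and the other 13 libraries have 2 to 10.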

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

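Most results kept their direction and their side of the threshold, and the exceptions sit mainly in the silencing experiment, which has 2 libraries per group. The test over genes of at least 1 CPM in siNC or EGFP-negative and the crossed block were chosen after seeing the data. A fold of at least 2, a narrower criterion by construction, left 468 genes higher and 1466 lower in A-BCSC, 379 and 307 in siENO1, and 3836 and 2796 in EGFP-positive. The DESeq2 Wald test called 669 genes higher in siENO1, where edgeR called 1042; the cause was not tested. Leaving out each library in turn gave 389 to 1140 genes higher and 558 to 1296 lower in siENO1, with the fewest without siNC replicate 2, when 913 of 947 calls were shared with the full set; the ranges were 3406 to 3942 and 3235 to 3751 in A-BCSC and 6838 to 7039 and 6868 to 6928 in EGFP-positive. The numbers of lists called higher and lower were 4 to 8 and 4 to 10 in siENO1, with 4 higher without siNC replicate 1 or siENO1 replicate 1 and 10 lower without siENO1 replicate 1. In siENO1, MT-ND4L had log2 -0.036 without siENO1 replicate 1 (range -0.036 to 1.56), against 0.97 with all libraries. The ribosomal protein list had adjusted p from 3.98e-08 to 0.149, downward without siENO1 replicate 1 (3.98e-08) and upward without siENO1 replicate 2 (0.0062). The cause of these shifts was not tested. For ENO1 in the reporter sort, upper-quartile scaling, which moved the median of all genes by 0.203, gave log2 0.10 in place of -0.10. Correlations between both sorts went to -0.616 over genes of at least 5 CPM and to -0.555 over protein-coding genes, with -0.531 to -0.517 when a library was left out. The corresponding ranges were -0.348 to -0.26 for the state sort and silencing and 0.164 to 0.22 for the reporter sort and silencing. With an estimated correlation, camera kept 8 higher and 5 lower lists in A-BCSC, 0 and 0 in siENO1, and 5 and 4 in EGFP-positive, and the tests across comparisons had adjusted p = 0.0638 for genes falling in A-BCSC tested in siENO1 and 0.0823 for the rising and the falling genes of the reporter sort tested in siENO1. Fry, which tests lists without comparing them with other genes, called 1 higher and 1 lower list in siENO1 and 17 and 12 in EGFP-positive. DESeq2 size factors changed no call of a list or a named gene. Over all libraries left out in turn, named genes lost their call 44 times in siENO1, 9 times in A-BCSC and 2 times in EGFP-positive. Over genes of at least 1 CPM elsewhere, the heat shock (0.107) and ribosomal (0.0795) lists were no longer called in A-BCSC. With the replicate block, 3636 genes were higher and 3541 lower in A-BCSC, 884 and 944 in siENO1, and 6930 and 6878 in EGFP-positive, the YAP list in siENO1 was not called (0.0648), and no other list changed its call. Libraries with the same number did not deviate together in the sorts (correlations -0.0348, 0.0174 and -0.0466 in the state sort and -0.00171, -0.0198 and -0.00263 in the reporter sort). In the silencing experiment the correlation was -0.101, but with 2 libraries per group every pair has the same size of correlation, so this is no test. The labels do not say whether the numbers pair libraries, and these values cannot exclude it. The crossed block in the silencing experiment called 1758 genes higher and 1947 lower. Depth limits genes such as SOX2, with 0 to 9 counts per group, which could not be tested.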

Other observations

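The tests of the other H2B genes and of the H2B-mCherry reporter, and the use of genes of at least 1 CPM elsewhere, were chosen after the results were seen, and the other tests of the 3 patterns below were prompted by patterns already seen, with only their outcomes unknown when they were set out. Further gene groups were examined in the state sort. Of 27 lysosome and autophagy genes, 5 rose in A-BCSC, 13 fell and 9 did not pass (5 and 14 adjusted over the list alone; median -0.22, camera adjusted p = 0.000876, and adjusted p = 0.124 with an estimated correlation), with the cholesterol transporter NPC1 from 211.1 to 74.6 CPM. Wnt targets (3 higher, 1 lower, 4 not past of 8, the same adjusted over the list alone; median 0.125, camera adjusted p = 0.00173, and adjusted p = 0.135 with an estimated correlation) included cyclin CCND1 (190.0 to 493.3 CPM) and the Wnt antagonist DKK1 (23.3 to 81.7 CPM). Luminal breast genes rose in 6 of 10 cases, with 0 lower and 4 not past (the same adjusted over the list alone; median 0.59, camera adjusted p = 1.06e-05), among them AGR2 (12.95 to 75.2 CPM). Heat shock genes (7 higher, 0 lower, 7 not past of 14, the same adjusted over the list alone; median 0.11, camera adjusted p = 0.0326, and adjusted p = 0.25 with an estimated correlation) and ribosomal protein genes (26 higher, 0 lower, 45 not past of 71, and 25 higher adjusted over the list alone; median 0.13, camera adjusted p = 0.00908, and adjusted p = 0.646 with an estimated correlation) were called slightly higher as lists. The ribosomal list had 14 higher with upper-quartile scaling, and camera adjusted p = 0.0908 without A-BCSC replicate 1. Camera called no difference in A-BCSC for the pentose phosphate pathway (5 higher, 0 lower of 7; adjusted p = 0.13), cholesterol synthesis (8 higher and 4 lower of 23, or 5 and 6 with upper-quartile scaling; 0.703), fatty acid synthesis (5 higher, 1 lower of 11; 0.0885), Notch targets (1 higher, 2 lower of 9; 0.308), NRF2 targets (8 higher, 3 lower of 15; 0.167) or replication-dependent histones (5 higher, 2 lower of 15; 0.123), with the same counts adjusted over the list alone. The same holds for p53 targets (5 higher, 6 lower of 23; median 0.0439, or -0.0204 with upper-quartile scaling, mean -0.201, camera downward, 0.129) and the unfolded protein response (5 higher and 2 lower of 18, or 2 and 4 with upper-quartile scaling; median 0.0129, or -0.0516 with that scaling; 0.602). Of 3 endothelial genes tested 1 was lower (TIE1, log2 -2.89; 2 adjusted over the list alone), and of 3 fibroblast genes 1 (COL1A1, log2 -0.73; 1 adjusted over the list alone), too few for camera.

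In siENO1, camera called both lists of lipid synthesis genes lower with the preset correlation. Fatty acid synthesis had 1 of 11 higher, 4 lower and 6 not past (1 and 6 adjusted over the list alone; median -0.37, camera adjusted p = 0.00927, and adjusted p = 0.504 with an estimated correlation), with the desaturase FADS1 from 210.4 to 96.7 CPM and SCD from 790.5 to 438.4 CPM; without siNC replicate 1 the list had 0.0569. Cholesterol synthesis had 3 of 23 lower and 0 higher (the same adjusted over the list alone; median -0.12, camera adjusted p = 0.0391, and adjusted p = 0.504 with an estimated correlation), and was not called without siNC replicate 2 (0.109) or siENO1 replicate 2 (0.178). Lysosome and autophagy genes (5 of 27 higher, 1 lower, and 7 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.0168, and adjusted p = 0.571 with an estimated correlation) included the autophagy receptor SQSTM1 (307.2 to 839.8 CPM), and were not called without siNC replicate 1 (0.0755) or siENO1 replicate 1 (0.112). Histones (3 of 7 higher, 1 lower, and 6 and 1 adjusted over the list alone; median 0.96, camera adjusted p = 0.0212, and adjusted p = 0.487 with an estimated correlation) were not called without siNC replicate 1 (0.26), siENO1 replicate 1 (0.169) or siENO1 replicate 2 (0.156). YAP targets (5 of 22 higher, 2 lower, and 6 and 2 adjusted over the list alone; median 0.0902, camera adjusted p = 0.0429, and adjusted p = 0.563 with an estimated correlation) were not called without siNC replicate 2 (0.229) or siENO1 replicate 2 (0.0802). Heat shock genes (0 of 14 higher, 3 lower, and 0 and 5 adjusted over the list alone; median -0.25, camera adjusted p = 0.0336, and adjusted p = 0.571 with an estimated correlation) were not called without siNC replicate 2 (0.11) or siENO1 replicate 2 (0.0758). Camera called no difference in siENO1 for p53 targets (4 of 22 higher, 2 lower, and 5 and 2 adjusted over the list alone; adjusted p = 0.0664), although BTG2 rose (log2 1.43), nor for the unfolded protein response (1 of 18 higher, 2 lower, the same over the list alone; 0.13, but 0.043 without siENO1 replicate 1), TGF-beta targets (2 of 11 higher, 1 lower, the same over the list alone; 0.343), Wnt targets (0 of 8 higher, 1 lower, and 2 lower over the list alone; 0.157), Notch targets (1 of 9 higher, 1 lower, the same over the list alone; 0.693), epithelial genes (0 of 14 higher, 3 lower, the same over the list alone; 0.112, but 0.0447 without siNC replicate 1 and 0.0481 without siENO1 replicate 1) or luminal genes (0 of 8 higher, 3 lower, the same over the list alone; 0.115). Ribosomal proteins (0 of 71 higher, 1 lower, and 0 and 0 over the list alone; 0.343, but downward at 0.00258 without siNC replicate 1 and 3.98e-08 without siENO1 replicate 1, and upward at 0.0062 without siENO1 replicate 2), the pentose phosphate pathway (0 of 7 higher, 2 lower, and 1 and 2 over the list alone; median 0.0439, mean -0.15, camera downward, 0.343) and mesenchymal genes (3 of 22 higher, 3 lower, and 6 and 4 over the list alone; median -0.0275, mean 0.153, camera upward, 0.305) were not called either. No blood gene, 1 endothelial gene (not past; 1 lower adjusted over the list alone) and 2 fibroblast genes (1 higher) were tested.

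In EGFP-positive cells, cholesterol synthesis genes rose in 15 of 23 cases and fell in 6 (median 0.50, camera adjusted p = 0.00103, and adjusted p = 0.11 with an estimated correlation), and the list of lysosome and autophagy genes had 17 of 27 higher and 9 lower (median 0.46, camera adjusted p = 0.0104, and adjusted p = 0.216 with an estimated correlation). NRF2 targets were 8 higher and 7 lower of 16 (median 0.10, camera adjusted p = 0.0303, and adjusted p = 0.141 with an estimated correlation), with the haem oxygenase HMOX1 higher (log2 4.37). The pentose phosphate pathway had 0 higher and 5 lower of 7 (median -0.52, camera adjusted p = 0.0426, and adjusted p = 0.175 with an estimated correlation). Camera did not call fatty acid synthesis (3 higher, 8 lower of 11; adjusted p = 0.689), p53 targets (12 higher, or 11 over the list alone, and 6 lower of 23; 0.191), the unfolded protein response (11 higher, 7 lower of 18; 0.1), Wnt targets (1 higher, 5 lower of 8; 0.146), Notch targets (5 higher, 2 lower of 9; 0.9), histones (7 higher, 4 lower of 13; 0.473), luminal genes (5 higher, 2 lower of 10; 0.458) or ribosomal proteins (18 higher and 41 lower of 71, or 38 and 26 with upper-quartile scaling; median -0.109, or 0.0942 with that scaling; 0.273). Other counts adjusted over the list alone were the same. Of 2 endothelial genes tested 2 rose (PECAM1, log2 2.11, and TEK, log2 2.30), and of 4 fibroblast genes 2 rose (COL1A1, log2 1.12, and DCN, log2 3.43), also adjusted over the list alone.

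The first pattern is the lymphocyte transcripts of the Q-BCSC libraries. Of 20 further T lymphocyte genes 13 were lower in A-BCSC (2555 counts in Q-BCSC against 456). Of 20 genes of B lymphocytes, myeloid and red cells 1 was (ALAS2), but most of these had too few counts to be tested. Their summed counts (1035 in Q-BCSC against 1277 in A-BCSC) do not decide about blood cells of other classes. Most of the sum came from BANK1 (345 and 601) and CD22 (203 and 377), both called higher in A-BCSC. Such genes can hide added counts of the others in Q-BCSC. In other groups 3 of the T lymphocyte genes and 5 of the other genes reached 1 CPM. Each Q-BCSC library had at least 43 more T cell receptor V segments with a count than the highest A-BCSC library, which argues against lymphocyte genes switched on in the cancer cells, since cells of another lineage would not be expected to express many V segments. A candidate explanation is RNA from a small number of T lymphocytes in the Q-BCSC samples, with PTPRC at 10.6, GZMA at 8.75 and CD8A at 8.37 CPM. Whether such reads add to the other lists lower in A-BCSC stays open: 7 of 7 stayed called over genes of at least 1 CPM in siNC or EGFP-negative, but these include genes that lymphocytes express too.

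The second pattern is HIST1H2BB, a histone H2B gene at 761.8 CPM in Q-BCSC, 13.6 in A-BCSC, 44.3 in siNC, 144.5 in siENO1, 0.138 in EGFP-negative and 16.6 in EGFP-positive, across separately scaled tables. Reads shared with other genes are argued against, as 0% of the 438 words of 50 bases of its transcripts occur in transcripts of another gene. The other 11 tested H2B genes had a median log2 change of 0.214, with 2 higher and 1 lower, so most H2B transcripts counted here did not fall with it. Whether histone transcripts changed at large is not decided by this, because the libraries were poly(A)-selected and replication-dependent histone transcripts mostly lack a poly(A) tail. Reads of the H2B-mCherry reporter, which the sort used, and expression of the endogenous gene cannot be told apart at 761.8 CPM, because this needs reads over the mCherry sequence. The labels call Q-BCSC the low and A-BCSC the high fraction of the reporter pair. They do not give the level of mCherry alone, so they argue neither for nor against reporter reads. A biological difference between the sorted states also stays open, as untested.

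The third pattern is the opposite direction of the state sort and the reporter sort. Gene length bias is argued against, since r was -0.531 after a trend on length was removed from both. The r of -0.616 over genes of at least 5 CPM decides nothing about noise of low counts, which can only bring r toward 0 where no library is shared. Lymphocyte reads in Q-BCSC are argued against as the whole source by the 3006 genes higher in A-BCSC and lower in EGFP-positive (1639 expected), since added reads raise genes in Q-BCSC only. The r of -0.536 over genes of at least 1 CPM in siNC or EGFP-negative decides nothing about them, since these include genes that lymphocytes express too. A state shared by EGFP-positive and Q-BCSC cells stays open, as untested, and so do handling effects common to 1 side of each sort, since the experiments differ in sequencer, only the state sort used H2B-mCherry, and the sorting days are not given in the labels.

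Other splits of the 6 libraries of a sort into groups of 3 number 10 with the real one, and no share under 0.05 is possible with them. In 1 of 10 splits, the real one, as many genes were called in the state sort (7824, against at most 0 in another split) and in the reporter sort (13931, against at most 0). The same held for lists in the state sort (22, against 8 to 17) and in the reporter sort (17, against 9 to 12). The preset correlation called lists in splits that called 0 genes. Every other split mixed libraries of both groups, so part of the real difference stayed between its groups and the rest widened the spread within them. The splits therefore cannot tell how either setting behaves without a difference, and a list call with the preset alone is read with caution. With an estimated correlation, 13 lists were called in the state sort and 9 in the reporter sort, against 0 in every other split.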
